A study of Homo sapiens with 10 samples.

How the data were processed

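RNA was measured in 10 libraries of MRC5 cells, a human lung fibroblast line. Of these, 5 came from cells given medium conditioned by non-stretched A549 cells (static medium) and 5 from cells given medium conditioned by stretched A549 cells (stretch medium). A549 is a human lung adenocarcinoma line with features of alveolar epithelium. The labels differ on the time of exposure: the sample descriptions state 24 hours and the series design states 6 hours before RNA was collected, so the time is not settled here.

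Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Ion AmpliSeq Transcriptome Human Gene Expression kit, which amplifies short targets by multiplex PCR. The protocols mention no molecular identifiers, so counts are of amplified reads, not of independent molecules, and limits from counting cover counting error only. Per the submitters' processing notes, fastp 0.20.1 and Salmon 1.9 were used and the build was hg38/GRCh38. The role of each tool, the annotation, the use of strand and any step that made estimates whole are not given in the sources used here. The deposited values were whole-number counts per Ensembl gene with no scaling, in 1 table of 14054 genes. In the table, the fewest libraries in which any gene was above 0 was 5, so genes seen in fewer libraries were not analysed here. Columns were matched to samples through the number in each sample title. Symbols were found for 13831 identifiers, and 223 kept their identifier. Gene positions are from GENCODE release 29 on GRCh38.

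Total counts ran from 4231653 (stretch 2) to 8455073 (static 3). A floor of 3 counts corresponded to 0.355 CPM (counts scaled to a common library size) in the deepest library and to 0.709 CPM in the shallowest. Within groups, pairs of libraries differed by 6.05 to 24.5 in chi-square per degree of freedom, above counting noise, so none was treated as a second deposit of the same library. This does not tell separate cultures from repeat preparations of one RNA. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

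Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM, and tested by the quasi-likelihood test for stretch minus static medium, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 10968 genes. CPM use TMM library sizes, and log2 CPM a prior count of 2. Intervals are 95% intervals of the fitted log2 fold change, ± after a fold change is its standard error, and ± after CPM is the SD over 5 libraries. Single values per library were compared by exact two-sided permutation tests over the 252 arrangements, which cannot give a p under 0.00794. Adjusted over 26 lists, no list can pass 0.05 in this test unless at least 5 lists pass together.

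Before the data were examined, 26 gene lists with 757 entries (721 distinct names, of which 561 were tested) were fixed from general knowledge of fibroblast activation, senescence, stress and possible other cells. Because 36 names stood in more than 1 list, the lists are not independent. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it. A list's mean log2 CPM per library, centred on its mean over 10 libraries, was tested by exact permutation, a test added after seeing the data. The rule for named genes, also fixed beforehand, took up to 8 rises and 8 falls past the threshold whose groups did not overlap, up to 4 called members of each list, 12 genes close to the study's question, the 10 smallest p-values where fewer than 10 genes were called, and the 2 smallest p-values of each called list without called members. It gave 29 genes. Of the 12 question genes, 11 were analysed. Some items that the rule takes are not reported here. In addition, 26 genes that passed when adjusted over their list alone were named after their values were seen.

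Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, library totals), no filter, a filter of 50 counts in 5 libraries, DESeq2 1.42.0, limma-voom, a threshold of 0.1, the title number as a covariate or in consecutive pairs as a block, 1 surrogate variable from sva 3.50.0, and each library left out. Added after seeing the data were thinning to the smallest total, the robust quasi-likelihood fit, merging of ribosomal protein pseudogenes with their parents, and the permutation test of lists. The groups share no title number, so no paired design was used. Positions show which annotated genes overlap, but not whether reads were split between them. Of the genes named here, RPL21P53 overlaps HSPA4L, HINT1 overlaps LYRM7, SLC25A12 overlaps HAT1 and METAP1D, RPL5 overlaps FAM69A, and ACTA2 overlaps STAMBPL1 and FAS. TGFB1 overlaps HNRNPUL1 and CCDC97, IL6 overlaps STEAP1B, SPHK1 overlaps PRPSAP1, IGFBP7 overlaps POLR2B, RPL6 overlaps PTPN11, and RPL10 overlaps DNASE1L1. These partners are in the table of counts.

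The procedure was tested on counts simulated from these libraries, over 10864 genes. Each gene was drawn independently of the others, and the 200 single genes to be changed were taken from the more abundant ones. At a log2 fold change of 0.5, 32% of 50 changed genes were recovered, at 1 and at 1.5 98% each, and at 2 100%. Calls numbered 190: 164 of the 200 changed genes, 9 of the 31 members of 1 list shifted as a whole, and 17 of 10633 unchanged genes. The shifted list was called and 0 other lists were. Because the simulated genes were uncorrelated, this does not show how often camera calls unshifted lists in real libraries. The shares recovered apply to abundant, independently varying genes only, in a run where 200 single genes and 1 list were changed.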

Results

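Gene expression was measured in MRC5 human lung fibroblasts given medium from stretched or from non-stretched A549 epithelial cells, with 5 libraries per group. The series asks whether mechanical stretch makes alveolar epithelial cells senescent and whether such cells activate fibroblasts through secreted factors, and this comparison addresses the fibroblasts' response. Libraries held 6675921 ± 1494760 counts with static medium and 5948227 ± 1544115 with stretch medium (SD, n = 5 each), a difference within the spread between libraries (exact permutation test, two-sided p = 0.444). Between 13180 and 13663 of the 14054 genes were above 0 in a library, and the 10 most abundant genes held 4.46% to 5.12% of counts.

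No single gene separated the groups at the chosen threshold, while gene sets of amino acid metabolism, sterol metabolism, ribosomal proteins and p53 targets moved to one side in the primary list test. None of these 4 list calls held with an estimated correlation (adjusted p = 0.625 for the p53 list and 0.786 for each of the others). In edgeR's quasi-likelihood test, 0 of 10968 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.0840. At an unadjusted p under 0.05 there were 1804 genes, 886 higher and 918 lower with stretch medium, where 548 would be expected by chance. DESeq2 called 269 genes, 126 higher and 143 lower, and limma-voom called 1. Over other splits of the libraries into 5 and 5, DESeq2 called up to 123 genes and edgeR up to 4. A DESeq2 call alone therefore does not settle a single gene. Groups did not overlap for 408 genes, 3.72% of those tested, against 0.794% by chance. Without stretch 4 the edgeR count was 39 genes, without stretch 6 it was 2 and without stretch 10 it was 1. The biological coefficient of variation was 17.5%. The first principal component held 24.8% of the variance and its scores averaged -13.0 with static and 13.0 with stretch medium (exact permutation test, two-sided p = 0.0238).

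The 10 genes with the smallest p-values were lower with stretch medium and did not overlap between groups, but none passed the threshold in edgeR (adjusted p = 0.0840 for each). FKBP8, a membrane-anchored immunophilin that restrains apoptosis (chromosome 19, 18531751 to 18544077), was at 27.6 ± 3.76 CPM with static and 15.2 ± 2.95 CPM with stretch medium, a log2 fold change of -0.86 ± 0.16. ABCC9, a regulatory subunit of ATP-sensitive potassium channels (chromosome 12, 21797401 to 21942529), was at 41.1 ± 7.24 and 20.7 ± 6.25 CPM, or -0.995 ± 0.184. SARS1, the cytosolic seryl-tRNA synthetase (chromosome 1, 109213918 to 109238169), was at 80.5 ± 14.996 and 46.1 ± 8.20 CPM, or -0.80 ± 0.15. LMO4, a LIM-only transcriptional cofactor (chromosome 1, 87328468 to 87348923), had a log2 fold change of -0.72 ± 0.14. The nucleotide hydrolase HINT1, the most abundant of the 10, was at 420 ± 52.2 and 276 ± 35.5 CPM. The linker histone gene H1-4 was at -0.63 ± 0.12, the glutamate receptor accessory gene SHISA9 at -0.83 ± 0.16, the sulfate donor synthase PAPSS2 at -1.05 ± 0.20 and the mitochondrial aspartate-glutamate carrier SLC25A12 at -1.001 ± 0.195. DESeq2 called 9 of the 10, with adjusted p from 0.000773 for FKBP8, ABCC9 and LMO4 to 0.00356 for PAPSS2. Without stretch 4, edgeR's adjusted p was under 0.05 for 9 of the 10: 0.0135 for ABCC9, 0.0196 for SHISA9, 0.0362 for LMO4, HINT1, H1-4, SLC25A12 and RPL21P53, 0.0480 for FKBP8 and 0.0496 for SARS1. That of PAPSS2 was 0.0516. Without stretch 6, that of FKBP8 was 0.0252.

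The tenth gene, RPL21P53, is a processed pseudogene of the ribosomal protein gene RPL21 and lies within the bounds of HSPA4L on the opposite strand (chromosome 4, 127812720 to 127813200). It was at 75.3 ± 38.0 CPM with static medium. With stretch medium it had 0 counts in every library but stretch 6, at 15.3 CPM. It is 1 of 13 near-identical RPL21 copies in the table, so its level is uncertain. DESeq2 gave an adjusted p of 0.187, limma-voom 0.0146, and edgeR 4.00e-05 without stretch 6 and 0.0362 without stretch 4. The summed CPM of the copies were 1486 ± 218 and 1289 ± 536 (exact permutation test, two-sided p = 0.540).

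**Figure D1:**
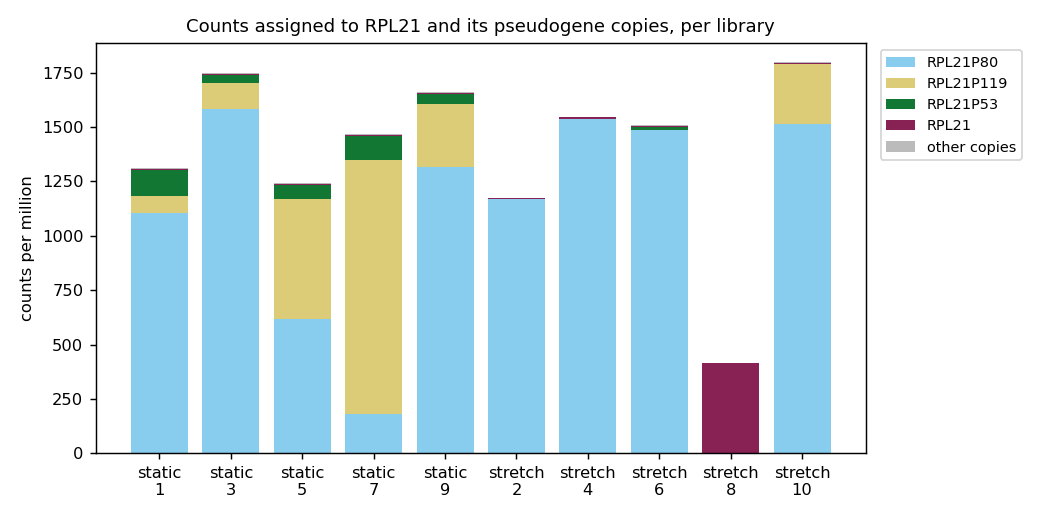
CPM (vertical axis, from 0) assigned to RPL21 and its pseudogene copies in each of the 10 libraries (horizontal axis), stacked by copy. RPL21P53 was above 0 in each static library and in stretch 6, and in stretch 8 the parent RPL21 held 412 CPM while RPL21P80 held 1.55 CPM.

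Of the 11 question genes analysed, on fibroblast activation, secretion and the cell cycle, 7 were higher and 4 lower with stretch medium. None passed the threshold over all genes. ACTA2, the smooth muscle actin of myofibroblasts (chromosome 10, 88935074 to 88991339), was at 173 ± 22.6 CPM with static and 216 ± 36.3 CPM with stretch medium. Its log2 fold change was 0.32, with an interval of 0.05 to 0.60 (adjusted p = 0.244). COL1A1, the main chain of type I collagen (chromosome 17, 50183289 to 50201632), was at 2749 ± 246 and 3211 ± 333 CPM, a log2 fold change of 0.22 with an adjusted p of 0.273. The fibronectin gene FN1 had a log2 fold change of 0.30 (0.04 to 0.56, adjusted p = 0.252). CCN2, which encodes connective tissue growth factor (chromosome 6, 131948176 to 131951373), was at 302 ± 27.0 and 382 ± 42.9 CPM, with an adjusted p of 0.146. The proliferation marker MKI67 was at 0.35 (0.08 to 0.62, adjusted p = 0.196), and the neutrophil chemokine CXCL8 at -0.89 (-1.50 to -0.28, adjusted p = 0.157). These 6 genes had an unadjusted p under 0.05, and of them only CXCL8 was lower with stretch medium. The intervals of the other 5 spanned 0: COL3A1 from -0.41 to 0.12, the matrix protein gene POSTN from -0.38 to 0.09, TGFB1 from -0.12 to 0.29, IL6 from -0.62 to 0.36 and the cell-cycle inhibitor CDKN1A from -0.23 to 0.35. Without static 3 the IL6 estimate was 0.11, and without static 7 that of CDKN1A was -0.044.

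**Figure D2:**
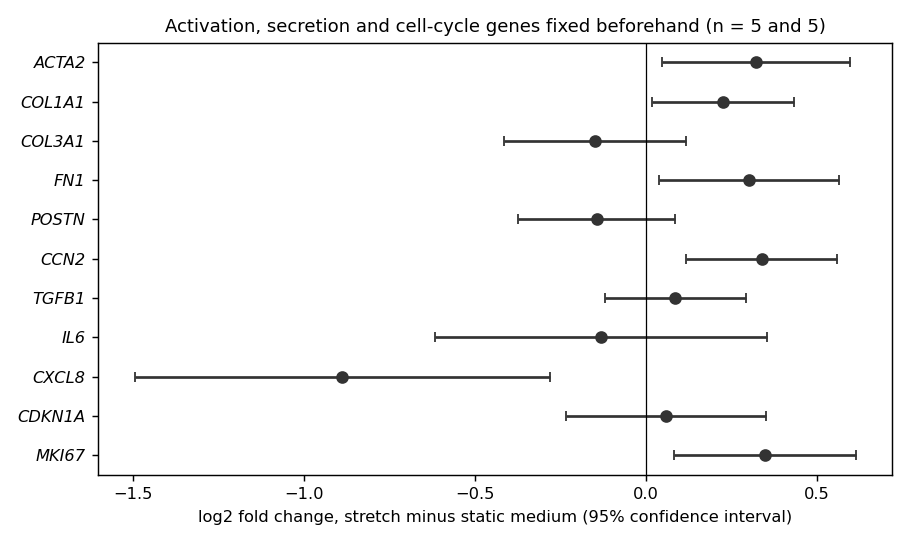
Log2 fold change, stretch minus static medium (horizontal axis), of the 11 question genes analysed, with 95% intervals from edgeR's fit on 5 libraries per group. The intervals of ACTA2, COL1A1, FN1, CCN2 and MKI67 lie above 0 and that of CXCL8 below 0, before adjustment for the number of genes.

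The matrix and contractile lists were not called as groups by camera. The 18 contractile and cytoskeletal genes tested had a median log2 fold change of 0.13 (12 above 0, adjusted p = 0.405), and 0 passed when adjusted over the list alone. Of 29 collagen and matrix genes, with a median of 0.069 and an adjusted p of 0.391, 1 rose when adjusted over the list alone and 0 over all genes. It was TNC, the adhesion-modulating glycoprotein tenascin-C, at 46.4 ± 9.18 CPM with static and 76.0 ± 19.4 CPM with stretch medium, or 0.71 ± 0.18. In the contractile list and in the collagen and matrix list, each member with an unadjusted p under 0.05 in edgeR was higher with stretch medium. The 18 collagen processing genes had a median of 0.10 (adjusted p = 0.391), with 0 past the list-alone threshold. Among 18 matrix proteases and inhibitors (adjusted p = 0.636), the aggrecanase gene ADAMTS1 rose by that count, at 0.45 ± 0.13. The median of 0.035 and the mean of -0.011 of this list differed in sign. Among 26 TGF-beta responsive genes, with a median of -0.095 and an adjusted p of 0.893, the sphingosine kinase gene SPHK1 rose over the list alone, at 0.63 ± 0.15. Among 19 YAP/TAZ targets (median 0.011, adjusted p = 0.767), AMOTL2, an angiomotin family gene, rose at 0.47 ± 0.14 and CCN2 at 0.34 ± 0.11, while the tissue factor gene F3 fell at -0.48 ± 0.15, over the list alone. DESeq2 called TNC, ADAMTS1, SPHK1 and AMOTL2 over all genes, and gave CCN2 an adjusted p of 0.0508. TNC, ADAMTS1, SPHK1, AMOTL2 and F3 were named after their values were seen.

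**Figure D3:**
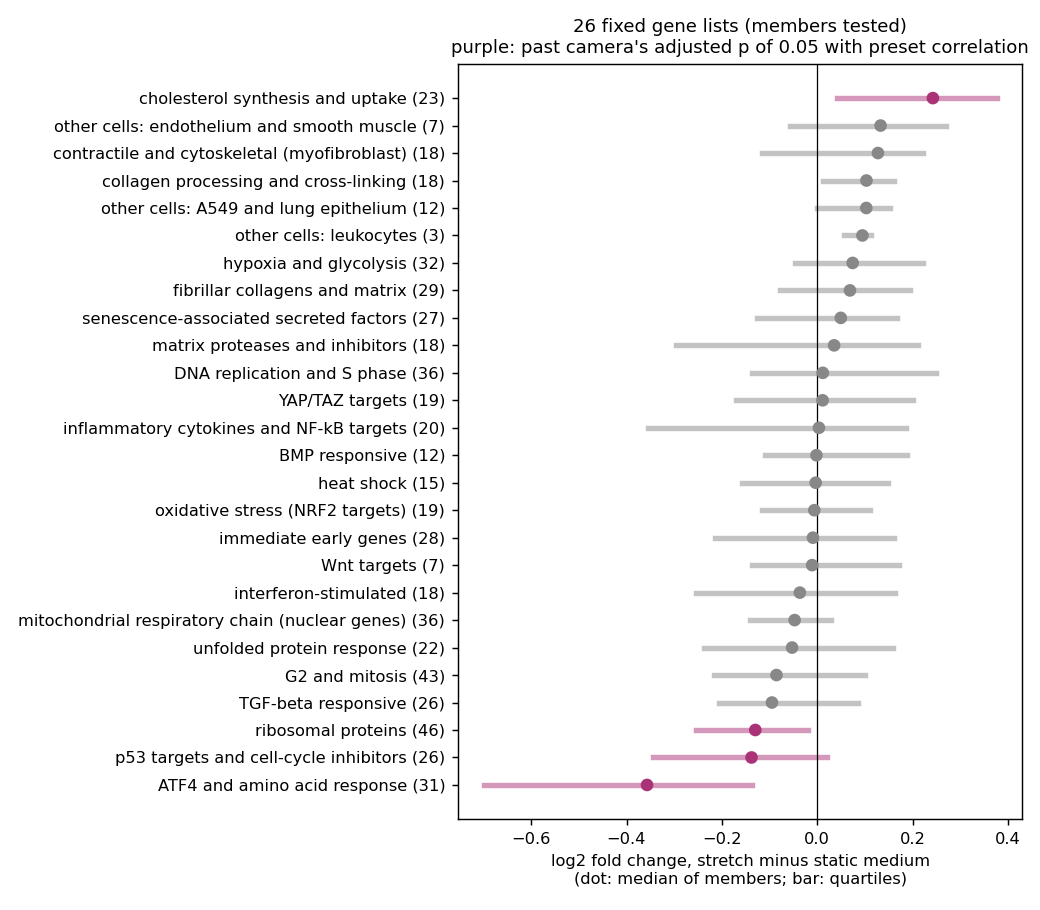
Median (dot) and quartiles (bar) of the log2 fold change, stretch minus static medium (horizontal axis), of the members tested in each of the 26 fixed lists. Purple marks the 4 lists past an adjusted p of 0.05 in camera with the preset correlation, from -0.36 for the ATF4 and amino acid list to 0.24 for the cholesterol list; with an estimated correlation 0 lists passed.

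Genes of the amino acid response driven by the transcription factor ATF4 were lower with stretch medium as a list in camera with the preset correlation (adjusted p = 2.89e-09). The call was lost with an estimated correlation (adjusted p = 0.786) and in fry (adjusted p = 0.295). Of 31 tested, 28 had a log2 fold change below 0, and the median was -0.36. Adjusted over the list alone, 9 fell and 0 rose, and over all genes 0 passed. They included the transcription factor CEBPB (-2.04 ± 0.40), the serine synthesis enzymes PSAT1 (-1.32 ± 0.28) and PSPH (-0.77 ± 0.18), asparagine synthetase ASNS (-1.52 ± 0.34) and the cystathionine lyase CTH (-1.39 ± 0.30). The others were the glycyl-tRNA synthetase GARS1 (-0.48 ± 0.12), the glutathione-degrading enzyme CHAC1 (-0.79 ± 0.21), the pseudokinase TRIB3 (-0.97 ± 0.30) and the tRNA exporter XPOT (-0.32 ± 0.12). PSAT1 (chromosome 9, 78297143 to 78330093) was at 217 ± 104 CPM with static and 86.7 ± 20.3 CPM with stretch medium. CEBPB (chromosome 20, 50190734 to 50192689) was at 4.77 ± 1.72 and 1.13 ± 0.845 CPM, close to the counting floor. CEBPB and PSAT1 were named by the rule, and the other 7 after their values were seen. DESeq2 called 5 members of the list, each lower, and gave no adjusted p for CEBPB and CTH. In edgeR, the adjusted p of CEBPB without stretch 4 was 0.0270.

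With the preset correlation, camera also called the ATF4 list in each fit that left out a library (adjusted p from 3.26e-14 to 5.97e-05). The list's mean log2 CPM was 0.22 ± 0.33 with static and -0.22 ± 0.12 with stretch medium (SD, n = 5 each; exact permutation test, two-sided p = 0.0238, adjusted p = 0.206 over 26 lists). Single static libraries lay at 0.51, 0.59, -0.097, 0.20 and -0.11 for static 1, 3, 5, 7 and 9, so static 5 and 9 lay inside the range of the stretch libraries, -0.40 to -0.078.

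**Figure D4:**
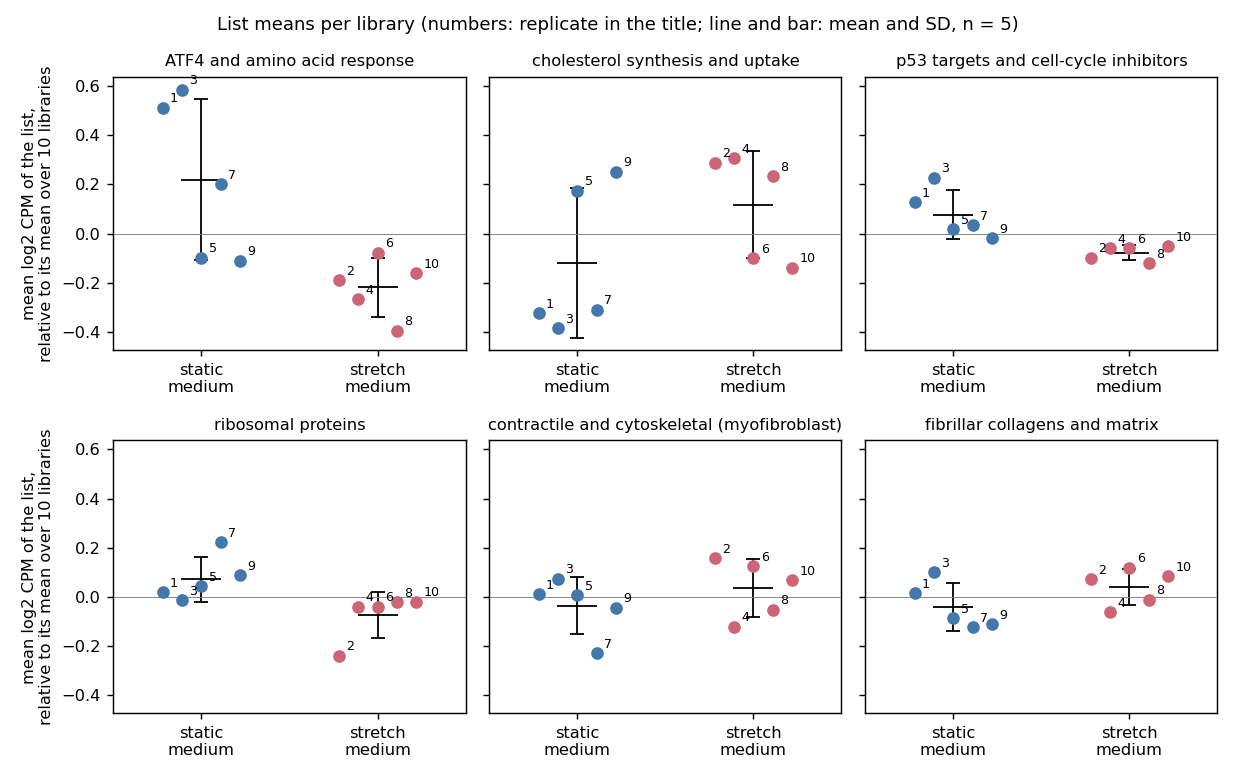
Mean log2 CPM per library of 6 lists, each relative to its own mean over the 10 libraries (vertical axis), for static and stretch medium; numbers are those in the sample titles, and the line and bar are mean and SD of 5 libraries. Groups did not overlap for the p53 and ribosomal protein lists, and overlapped for the ATF4, cholesterol, contractile and matrix lists.

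Genes of cholesterol synthesis and uptake were higher with stretch medium as a list in camera with the preset correlation (adjusted p = 0.00348). The adjusted p was 0.786 with an estimated correlation and 0.459 in fry. Of 23 tested, 17 had a log2 fold change above 0, and the median was 0.24. Adjusted over the list alone 2 rose and 0 fell, and over all genes 0 passed. Of these, CYP51A1, the sterol demethylase of the pathway (chromosome 7, 92112151 to 92134803), was at 51.9 ± 8.67 CPM with static and 91.4 ± 39.9 CPM with stretch medium, or 0.81 ± 0.24, and was called by DESeq2 (adjusted p = 0.0281). With a library left out, camera's adjusted p ranged from 9.82e-06 to 0.171, and the call was lost without static 3 (0.171) and without stretch 4 (0.0769). The list means of the groups, -0.12 ± 0.30 and 0.12 ± 0.22 (SD, n = 5 each), were not separated by the exact permutation test (two-sided p = 0.206).

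**Figure D5:**
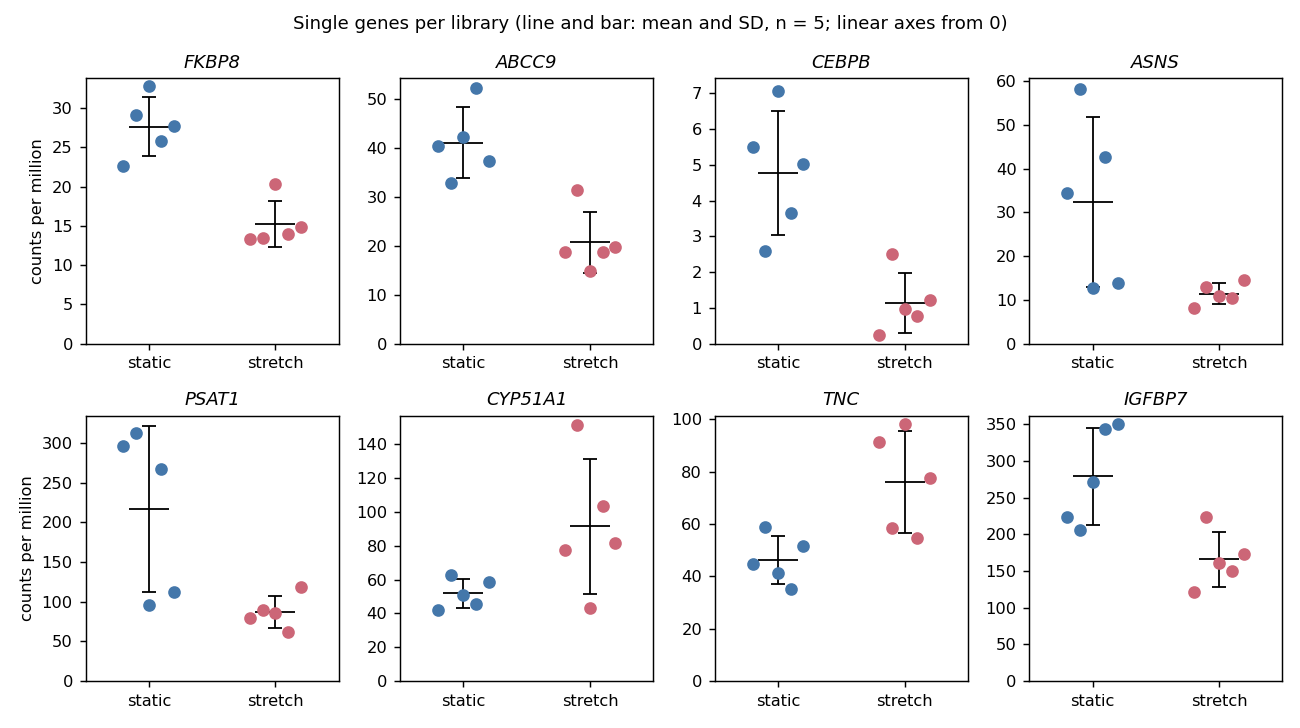
CPM (vertical axes, linear from 0) of 8 genes in each library with static and stretch medium; lines and bars are mean and SD of 5 libraries. FKBP8, ABCC9 and CEBPB did not overlap between groups, while ASNS, PSAT1, CYP51A1, TNC and IGFBP7 did, and the 8 genes were picked for plotting after their values were seen.

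Genes of p53 signalling and cell-cycle arrest were lower with stretch medium as a list in camera with the preset correlation (adjusted p = 0.0355). The adjusted p was 0.625 with an estimated correlation and 0.174 in fry. Of 26 tested, 19 lay below 0, with a median log2 fold change of -0.14. The p53 targets CDKN1A and MDM2, picked here after their values were seen, were at 0.058 and -0.032, with intervals that spanned 0. Over the list alone 2 fell and 0 rose, and over all genes 0 passed. TP53I3, a quinone oxidoreductase induced by p53 (chromosome 2, 24077433 to 24085861), was at 59.9 ± 18.3 CPM with static and 39.2 ± 4.39 CPM with stretch medium. TIGAR, a p53-induced regulator of glycolysis (chromosome 12, 4307763 to 4354593), was at 33.0 ± 7.05 and 21.5 ± 4.91 CPM. DESeq2 called both. Camera's adjusted p ranged from 0.00796 to 0.267 with a library left out. It became 0.267 without static 3, 0.0807 without static 1, 0.0870 without stretch 4, 0.0648 without stretch 8 and 0.0620 after thinning to the smallest library total. The list means did not overlap between groups (exact permutation test, two-sided p = 0.00794, the smallest the design can give, adjusted p = 0.103).

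Inflammatory genes and secreted factors of senescence were not called as lists. Of 20 inflammatory and NF-kB target genes (adjusted p = 0.554), 4 fell over the list alone and 0 rose. They were CXCL8, the apoptosis inhibitor BIRC3 (-0.88 ± 0.27), the NF-kB inhibitor TNFAIP3 (-0.86 ± 0.28) and the adhesion molecule ICAM1 (-0.75 ± 0.25), at mean levels of 1.81 to 20.4 CPM. The list's median of 0.0036 had the opposite sign of its mean, -0.14, and of the test. Of 27 secreted factors (median 0.049, mean -0.045, tested direction lower, adjusted p = 0.978), 1 fell over the list alone. It was the growth factor binding protein IGFBP7, at 279 ± 66.3 CPM with static and 166 ± 37.7 CPM with stretch medium, which DESeq2 called and which edgeR called without stretch 4 (adjusted p = 0.0362). BIRC3, TNFAIP3, ICAM1 and IGFBP7 were named after their values were seen.

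Ribosomal protein genes were lower with stretch medium as a list in camera with the preset correlation (adjusted p = 0.00115). The adjusted p was 0.786 with an estimated correlation and 0.300 in fry. Of 46 tested, 36 lay below 0, with a median log2 fold change of -0.13. Over the list alone 7 fell and 0 rose, and over all genes 0 passed. RPL5 (chromosome 1, 92831983 to 92841924) was at 880 ± 152 CPM with static and 618 ± 78.6 CPM with stretch medium, and RPL8 (chromosome 8, 144789765 to 144792587) at 101 ± 19.6 and 69.2 ± 10.9 CPM. The others, RPL6, RPL10, RPL24, RPL19 and RPS20, ranged from -0.60 to -0.33 and were named after their values were seen. DESeq2 called 3 of the list, each lower. Camera's adjusted p was 0.000160 to 0.0381 with a library left out. The list means did not overlap (exact permutation test, two-sided p = 0.00794, adjusted p = 0.103). Stretch 2 stood apart, at -0.24 against -0.040 to -0.019 in the other stretch libraries.

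Cell-cycle lists were not called over the 10 libraries. The 36 DNA replication genes had a median of 0.012 and an adjusted p of 0.391, which was 0.0155 without static 7 and up to 0.723 without another library, and the 43 genes of G2 and mitosis a median of -0.086 and an adjusted p of 0.523. In neither did a member pass over the list alone. Of 22 unfolded protein response genes (median -0.053, adjusted p = 0.695), the transcription factor XBP1 (-0.45 ± 0.11) and the mannosidase-like gene EDEM1 (-0.56 ± 0.16) fell and SEL1L, of the degradation machinery for misfolded proteins, rose (0.33 ± 0.088) over the list alone. DESeq2 called the 3. Of 28 immediate early genes (median -0.0089, adjusted p = 0.695), the transcription factor KLF10 fell over the list alone, at -0.72 ± 0.16. KLF10 was called by DESeq2 and, in edgeR, without stretch 4 (adjusted p = 0.0340). Of 7 Wnt targets (median -0.011, mean 0.041, adjusted p = 0.695), the secreted inhibitor DKK1 rose over the list alone, at 0.43 ± 0.14. Over all genes its adjusted p was 0.159 in edgeR and 0.0709 in DESeq2. XBP1, EDEM1, SEL1L, KLF10 and DKK1 were named after their values were seen.

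In the remaining lists, 0 members passed over the list alone. Medians were 0.074 for hypoxia and glycolysis (adjusted p = 0.518, and 0.0469 without static 1 to 0.861 without another library), -0.036 for interferon-stimulated genes (0.808) and -0.047 for the nuclear genes of the respiratory chain (0.391). NRF2 targets, heat shock genes and BMP responsive genes had medians of -0.0060, -0.0031 and -0.0016, opposite in sign to their means and tests, and an adjusted p of 0.808 each. Markers of other cells were not called. Of the A549 and lung epithelium markers, 12 of 36 were tested, with 9 above 0, a median of 0.10 and an adjusted p of 0.518. The keratin gene KRT18 was at 11.2 CPM with static and 14.6 CPM with stretch medium, a log2 fold change of 0.40 (0.02 to 0.78, unadjusted p = 0.0384, adjusted p = 0.276). The epithelial adhesion gene EPCAM was at 2.81 and 2.80 CPM. Both were picked after their values were seen. Leukocyte markers (3 of 20 tested) had a median of 0.095 and an adjusted p of 0.808, and endothelial and smooth muscle markers (7 of 20 tested) a median of 0.13 and an adjusted p of 0.518.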

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

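Tests chosen only after the result was seen were the test of shared reads between RPL21 copies, the permutation tests of lists, the counts of splits for the ATF4 and cholesterol lists, the count of splits for genes called by edgeR, and the thinning and merging alternatives. Among 166 checks for a library standing apart within its group, 9 did so, where about 8 would be expected by chance.

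For RPL21P53, stretch 6 was at 3.96 log2 CPM against -1.65 in each of the other stretch libraries. RPL21P119 held 77 to 1167 CPM in the static libraries and 0 in the stretch libraries other than stretch 10, at 277 CPM. Over the 5 static libraries, the SD of the copies' summed CPM was 0.303 of that expected if the copies varied independently (permutation p = 0.0188), as reads shared between near-identical copies would give. Over the 5 stretch libraries it was 0.776, and the sum was 416 CPM in stretch 8 against 1174 to 1798 CPM in the others. Sharing between copies therefore stays open as the source of the difference in RPL21P53, and so does an effect of the medium, which was not tested. For the ribosomal protein list, adding the counts of 87 pseudogenes to their parents left camera's adjusted p at 0.00157 with the preset correlation. It was 0.800 with an estimated correlation. For the call with the preset correlation, this argues against reads shared with these 87 as its cause. Copies not matched to a parent by name were not merged, so sharing with them was not tested.

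The lower ATF4 list and the higher cholesterol list could both come from a chance arrangement of 10 libraries. With the preset correlation, some list of the 26 reached a camera p as small as that of the ATF4 list in 16 of 100 splits, and as small as that of the cholesterol list in 71, counting the real one in each. The smallest p in another split was 4.64e-32. No such count was made for the other lists called. The camera p of the ribosomal protein list was larger than that of the ATF4 list, so at least the same 16 splits match it. That of the p53 list was larger than that of the cholesterol list, so at least the same 71 match it. Chance is therefore not excluded for these lists either. The exact permutation tests of the 2 lists gave p of 0.0238 and 0.206 before adjustment. Adjusted over 26 lists they were 0.206 and 0.447. The design lets no list pass 0.05 after adjustment unless at least 5 lists pass together. The ATF4 list was also above the smallest possible p of 0.00794, since static 5 and 9 lay inside the range of the stretch libraries. Its failure after adjustment is thus not due to that limit alone. The cholesterol list was not separated even before adjustment. After thinning to the smallest total the median log2 fold changes were -0.33 and 0.28. Thinning keeps each gene's expected share of its library, so this could hardly have come out otherwise. It does not test other differences that run with library size. Camera called 4 lists in the real grouping and as many or more in 44 of 100 splits of the libraries, counting the real one, with up to 9 lists in another split, so chance cannot be excluded for the number of lists called. The composition of the medium given to the fibroblasts stays open as an explanation and was not tested.

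The excess of small p-values stands apart from other splits of the libraries although edgeR called no gene at 0.05. Of 100 splits drawn from 126, 1, the real one, gave as many as 1804 genes with an unadjusted p under 0.05, and the highest other split gave 1547. For DESeq2's count of 269, again 1 of 100 did, and the highest other split gave 123. A chance arrangement of these libraries can thus be excluded for both counts at the share of 0.05. A chance difference between cultures cannot, because the labels do not say that the libraries of a group came from separate cultures. With 1 surrogate variable the first count was 1006, and the other splits were not fitted that way. For edgeR's count of 0 the splits say nothing, since 100 of 100 must give at least 0. The highest other split gave 4. The labels give no batch, so a difference in handling that ran with the medium is not excluded, and neither is an effect of the medium, which was not tested separately.

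Other libraries that stood apart are given as values. FKBP8 was at 4.37 log2 CPM in stretch 6 against 3.77 to 3.92 in the other stretch libraries. H1-4 was at 6.42 in static 9 against 5.99 to 6.10 in the other static libraries. POSTN was at 8.37 in static 7 against 8.74 to 8.86, and RPL24 at 9.48 in static 7 against 8.81 to 8.99. XPOT was at 8.09 in stretch 4 against 7.68 to 7.78. The mean log2 CPM of the Wnt list was -0.13 in stretch 4 against 0.048 to 0.092 in the other stretch libraries. That of the ribosomal protein list was -0.24 in stretch 2 against -0.040 to -0.019, and that of the leukocyte list -0.44 in stretch 8 against 0.077 to 0.27.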

How the results depend on the processing

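The thinning, the robust fit, the merging of copies and the permutation test of lists were chosen after seeing the data. The count of 0 genes called by edgeR was the same under the other scalings, the filters, the title number as covariate, the replicate block, 1 surrogate variable, thinning and the robust fit. It was 269 genes (126 higher, 143 lower) in DESeq2, 1 (lower) in limma-voom and 61 (16 higher, 45 lower) at a threshold of 0.1. With each library left out it ranged from 0 to 39 genes, with 0 to 6 higher and 0 to 33 lower: 39 without stretch 4, 2 without stretch 6, 1 without stretch 10 and 0 otherwise. The call without stretch 10 was RPL21P119, which was above 0 in no other stretch library. Those without stretch 6 were FKBP8 and RPL21P53, and RPL21P53 was above 0 in no other stretch library. The cause of the other calls was not tested. With 1 surrogate variable, 1006 genes had an unadjusted p under 0.05, against 1804 without. The largest shift of the median log2 fold change by another scaling was 0.017, and the split at an unadjusted p under 0.05 was 771 higher and 1027 lower with upper-quartile scaling. Consecutive title numbers as a replicate block left 0 genes, 1506 with an unadjusted p under 0.05, and 4 lists. The correlations of paired deviations were 0.022, -0.16, -0.12, 0.041 and -0.14, so no sign of pairing by consecutive numbers was seen. Other pairings were not checked, and the labels do not say whether samples were paired.

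Camera called 4 lists under each scaling and filter and with copies merged, and 3 after thinning. It called 2 to 5 with each library left out: 2 without static 3 and 2 without stretch 4. With an estimated correlation 0 were called, and in fry 0. In the permutation test 0 were, but there no list can pass unless at least 5 lists pass together, so its 0 says nothing about stability. Over the 55 named genes, 1151 of 1199 alternatives kept the direction and the side of the threshold, 45 brought a gene past it (30 of them in DESeq2, 12 without stretch 4) and 3 turned the direction, in 2 genes. IL6 ranged from -0.26 to 0.11 with each library left out. CDKN1A ranged from -0.044 to 0.13, and was -0.13 with 1 surrogate variable. Of the lists, 7 turned their direction in some fit without ever passing the threshold. With each library left out, their adjusted p ranged from 0.516 to 0.978 for TGF-beta responsive genes, 0.607 to 0.971 for secreted factors, 0.672 to 0.996 for interferon-stimulated genes, 0.315 to 0.991 for immediate early genes, 0.513 to 0.998 for NRF2 targets, 0.548 to 0.965 for heat shock genes and 0.579 to 0.996 for leukocyte markers, which were at 0.975 with no filter. The cause was not tested. Simulated changes of 0.5 on the log2 scale were recovered for 32% of the abundant, independently drawn genes that were changed. Smaller differences were therefore mostly not detectable in that setting. How strict the adjustment is depends on how many genes change, and many were changed there. In the real libraries ABCC9 at -0.995 and PSAT1 at -1.32 did not pass in edgeR either. The shares recovered may thus overstate what the real comparison could detect.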

Other observations

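Genes of fatty acid synthesis that share the regulator SREBP with the cholesterol genes had a higher mean with stretch medium before adjustment (exact permutation test, two-sided p = 0.0476), in a separate list of 10 of which 7 were tested. The fatty acid synthase gene FASN was at 113 ± 28.9 CPM with static and 182 ± 37.2 CPM with stretch medium, the desaturase SCD at 602 ± 115 and 840 ± 146 CPM, and the desaturase FADS2 at 678 ± 106 and 861 ± 64.3 CPM (SD, n = 5). Log2 fold changes were 0.69, 0.48 and 0.35, and none passed in edgeR over all genes (adjusted p = 0.109, 0.137 and 0.166). DESeq2 called FASN (adjusted p = 0.0106) and SCD (0.0462), and gave FADS2 an adjusted p of 0.0821. ACLY, FADS1, ELOVL6 and SREBF1 lay between -0.024 and 0.057. FASN, SCD and FADS2 were singled out after their values were seen.

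Hypotheses on 2 regulators were tested, each with its expected outcome written before the test. Higher SREBP activity with stretch medium would raise the mean of the fatty acid genes, and that mean was 0.234 higher (exact permutation test, two-sided p = 0.0476, adjusted p = 0.0952 over the 2 tests). This is consistent with the hypothesis at the unadjusted level and fails the correction. Lower ATF4 activity would lower the tRNA synthetase genes known to be induced by ATF4 relative to the other cytosolic ones, and the difference was -0.189 (exact permutation test, two-sided p = 0.159, adjusted p = 0.159). The sign was the one expected, but 10 libraries do not settle it. YARS1 had the lowest value of the 6, at -0.61.

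Values of the cholesterol list spread within both groups. Its means were -0.32, -0.38, 0.17, -0.31 and 0.25 in static 1, 3, 5, 7 and 9, and 0.29, 0.31, -0.10, 0.23 and -0.14 in stretch 2, 4, 6, 8 and 10. In fry's test for changes in either direction, 11 of 26 lists passed an adjusted p of 0.05, while in its test for a shared direction 0 did. Fry does not compare a list with the other genes, and 1804 of 10968 genes had an unadjusted p under 0.05 in edgeR. The 11 lists may therefore only reflect the excess over all genes, which was not tested. Static 7 and stretch 6 lay at the ends of the first principal component, at -39.1 and 30.9.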
